A study of Mus musculus with 12 samples.

How the data were processed

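Gene expression was measured on 12 Illumina mouse bead arrays in E14 mouse embryonic stem cells in which both alleles of Hdac1 and of Hdac2 carry loxP sites and which express CreER, a Cre recombinase activated by 4-hydroxytamoxifen (OHT). Per the labels, the cells were grown on gelatin without feeder cells in serum with LIF, exposed to OHT for 16 hours to induce the deletion, and sampled on days 0, 1, 2 and 3, with 3 arrays per day. Total RNA was labelled as biotinylated cRNA. The labels title day 0 with "+OHT" as well, whereas the series design calls day 0 wild type, so whether the day 0 cells met any OHT is not stated. No cells given OHT without the loxP sites, and no cells kept for the same number of days without OHT, are among the samples.

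The deposited non-normalized table gives an intensity for each of 45281 probes and each array, which is the mean bead signal on a linear scale, neither background subtracted nor scaled between arrays as far as the values show. Beside each intensity the deposited table gives a detection p-value, whose steps show that it is the share of 936 negative controls brighter than the probe. The authors used GenomeStudio, without a stated version or settings. A second deposited table gives an intensity on a linear scale that shares 1 distribution across the 12 arrays, as quantile normalization makes, with no background subtraction seen. How the authors normalized it is not stated, and it was used only as an alternative. No per-sample column of these tables was left unused (0 columns).

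Intensities were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, which takes the background from the detection p-values, with an offset of 16, and were analysed on the log2 scale. Probes were kept when detected at p under 0.01 on at least 3 of the 12 arrays, which 17337 probes were. The probe table of the series gave 1 gene symbol for 34885 probes, several for 18 and none for 10378. Of these, 34807 probes matched the RefSeq gene table by Entrez gene ID. That table is of assembly GRCm38.p6 and was used for names and chromosomes only, and 0 symbols were updated by it. Each gene was represented by its detected probe with the highest mean, which gave 9934 genes tested from 14940 probes. Of these genes, 3557 had more than 1 detected probe.

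A linear model with 1 mean per day was fitted to all 12 arrays with limma (lmFit and eBayes), so that the spread was shared by the 4 groups. The 5 comparisons were each later day against day 0, day 2 against day 1 and day 3 against day 2, all two-sided. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 9934 genes of that comparison, and limma's F test over the 3 coefficients tested any change across the days. Errors of fold changes are standard errors of limma, and errors of group means are SDs over 3 arrays. Where a probe was not detected on any array of 1 group, the fold is a lower bound against the detection limit. The number of arrays limits the precision of every value. The labels do not say that the 3 replicates of a day are separate cultures, so the p-values measure only the spread between these samples.

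Gene lists were tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists of a comparison. An estimated correlation and fry were alternatives. Lists needed at least 5 measured genes. Of their 870 symbols, 1 had no gene ID. The lists, written from general knowledge before the data were examined, were pluripotency factors, class I and other zinc-dependent HDACs, HDAC1/2 corepressor complex subunits, histone acetyltransferases, mitosis and chromosome segregation, DNA replication and S phase, CDK inhibitors, p53 target genes, apoptosis regulators, trophectoderm markers, primitive and visceral endoderm markers, primitive streak and mesoderm markers, neuroectoderm markers, primed epiblast markers, REST-repressed neuronal genes, germline genes, 2-cell-stage genes, genes reported to rise with HDAC inhibitors, histone genes, Polycomb complex subunits, DNA methylation machinery, imprinted genes, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, cholesterol biosynthesis, unfolded protein and integrated stress response, heat shock genes, immediate-early genes, interferon response, fibroblast markers, cytoskeleton and adhesion genes, and lysosome and autophagy. Some genes are in more than 1 list. Counts of changed members are given over all genes tested and, where stated, adjusted over the list alone.

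The comparisons, tests, lists and alternatives, except those named as added, and the rule for naming genes were chosen before the data were examined. By that rule, the genes named were the 8 largest rises and 8 largest falls of each later day against day 0, and the 5 largest of each kind between later days, among called genes whose 3 later arrays all lay on 1 side of the 3 earlier ones. Clone names and genes not detected in either group were passed over. The rule also names every member of the pluripotency and HDAC lists, and up to 4 called members of each other list with the largest change at day 3, or 2 where none was called. Probes detected per array were compared with an exact two-sided permutation test, for which 3 arrays against 3 cannot give a p under 0.1. Genes were also tested by chromosome with camera.

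Array numbers recur in every group, so pairing was checked by correlating, across genes, the deviations from the day means of arrays with the same number. For day 1 against day 0 these were 0.20, 0.26 and 0.44, and for day 3 against day 0 they were 0.26, 0.28 and 0.42, each over 0.1. For day 2 against day 0 they were 0.04, -0.03 and 0.25. For day 2 against day 1 they were 0.08, -0.02 and 0.26, and for day 3 against day 2 they were 0.35, 0.07 and 0.46. Genes are not independent replicates. The replicate number as a block was therefore an alternative rather than part of the model. The arrays also split by their background signal, with a lower quartile of 179.5 to 185.7 on 6 arrays (day 0 replicate 3, day 1 replicate 3, day 2 replicates 2 and 3, and day 3 replicates 2 and 3) and of 164.9 to 168.9 on the other 6.

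The alternatives were no background correction, cyclic loess, scaling to the 75th percentile or no scaling in place of quantile normalization, the deposited normalized table, no filter, detection on all 12 arrays or at p under 0.05, every probe as its own feature, only the arrays of the 2 groups compared, the replicate block, trend and robust variance, array weights, a fold of at least 1.5, an adjusted p under 0.01, and leaving out each array in turn. The background group as a block, fits within each background group, a fit without the arrays numbered 3, and the replicate block and left-out arrays for lists between later days were added after the data had been seen. The code was tested on simulated data shaped like the 9934 genes of day 3 against day 0. It recovered 11% of genes changed by 0.5 on the log2 scale and 91% of those changed by 1, and 5 of its 107 calls were false. A list shifted by 0.5 was called and 0 of the other lists were. Only 200 genes were changed there, against 3889 called in the data, so the threshold differed and these shares do not carry over. Noise was drawn independently for each gene, so false calls of lists of correlated genes were not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.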

Results

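Expression was measured on 12 arrays of Hdac1/Hdac2 conditional knockout mouse embryonic stem cells, with 3 arrays at each of days 0, 1, 2 and 3 of a course with OHT. Whether the day 0 cells met OHT is not stated. The upper quartile of the intensity, before normalization, ranged from 272.2 on day 3 replicate 2 to 382.2 on day 2 replicate 3. Between 14509 and 16770 of the 45281 probes were detected per array. After normalization the correlation between arrays across genes was 0.9796 to 0.9935 within a day and 0.9453 to 0.9927 between days. The first principal component held 50.9% of the variance and placed the arrays by day, from -30.1 to -25 at day 0, -16.1 to -15.7 at day 1, 8.3 to 10.6 at day 2 and 29.7 to 37.9 at day 3. With limma's F test, 3736 of the 9934 genes tested (37.6%) changed across the 4 days.

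The targeted genes were examined first. No probe of the table is named Hdac1. Hdac2 has 2 probes, and the source tables do not say whether either lies in the deleted part of the gene, so neither value checks the deletion. The brighter probe (ILMN_2640441) had a mean log2 intensity of 13.58 ± 0.16 (SD, n = 3) at day 0 and 13.32 ± 0.25 at day 3, a difference of -0.26 ± 0.14 with a limma adjusted p of 0.167 among all detected probes of named genes and of 0.149 in the fit with 1 probe per gene. In the latter fit it was -0.41 without day 3 replicate 3, which passed the threshold with a limma adjusted p of 0.0241, and it also passed with scaling to the 75th percentile, at -0.46 (0.00841). Over all 27 alternatives its adjusted p ranged from 0.00841 to 0.426. The dimmer probe (ILMN_1231785) had a mean of 6.46 ± 0.11 at day 0, where it was detected on 3 of 3 arrays. It was detected on 2 arrays at day 1, 1 at day 2 and 0 at day 3, where it was at least 1.3-fold lower than at day 0, with a limma adjusted p of 0.00384. Its comparisons at day 1 and day 2 did not pass, with limma adjusted p of 0.482 and 0.0679. Among the other deacetylases, Hdac8 was called lower at day 3, where it was undetected on all 3 arrays and at least 1.32-fold lower. Hdac5 (0.70) and Hdac3 (0.39) were called higher, as was Hdac11, which was undetected at day 0 (at least 1.05-fold). The Hdac8 call was lost without day 0 replicate 1 (limma adjusted p of 0.0653) and without day 3 replicate 2 (0.0674). Hdac4 (-0.35), Hdac6 (-0.29) and Hdac7 (0.27) were not called at day 3. Hdac4 passed without day 0 replicate 3 (0.0396) or day 3 replicate 3 (0.0443), and Hdac6 passed without day 0 replicate 3 (0.0217). Of the 8 members measured in the list of zinc-dependent HDACs, 3 rose and 1 fell at day 3, and these counts were the same adjusted over the list alone. The number of falls was 0 without day 0 replicate 1 or day 3 replicate 2, and 3 without day 0 replicate 3 or day 3 replicate 3.

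The comparison of day 1 with day 0 asks what changed first in the course. It gave 10 changed genes, of which 8 rose and 2 fell, with 994 genes at an unadjusted p under 0.05. The 3 later arrays did not overlap the 3 day 0 arrays for 17.2% of genes, where chance gives 10%. The largest measured change was a fall of Hmox1 (ILMN_2788073), from a mean log2 intensity of 8.42 ± 0.27 to 6.27 ± 0.41 (SD, n = 3). This was a change of -2.16 ± 0.23, 4.46-fold lower, with a limma adjusted p of 0.006. Hmox1 was also lower at day 2 (-2.40, limma adjusted p of 4.5e-05) and day 3 (-1.89). Myo10 fell by 0.69 on the log2 scale. Taf9b rose by 1.02 ± 0.12, with a limma adjusted p of 0.0071. Dmrtc2 and H2bfm, which were undetected at day 0, rose at least 2.09-fold and at least 1.43-fold. Snorc (0.86), Myl2 (0.86), Elavl3 (0.80) and Hmgn3 (0.67) also rose. All 10 genes were called in the same direction at days 2 and 3. These comparisons use the same 3 day 0 arrays, so part of this overlap can come from the shared controls. The covariance of the log2 fold changes across genes was 0.0627 for days 1 and 2 and 0.078 for days 1 and 3, against 0.0162 and 0.0163 in simulated arrays with no change. The simulated arrays were independent of each other, so they leave out the correlation of equally numbered arrays. The number of calls at day 1 rested on single arrays. It was 5 without day 0 replicate 1, 0 without day 0 replicate 2 (limma, with 1001 genes at an unadjusted p under 0.05), 1 without day 1 replicate 1, 2 without day 1 replicate 2 and 1 without day 1 replicate 3. It was also 3 without day 2 replicate 1, 2 without day 2 replicate 2 or 3, 3 without day 3 replicate 1, 4 without day 3 replicate 2 and 15 without day 3 replicate 3. Without day 0 replicate 2, Hmox1 and Taf9b each had a limma adjusted p of 0.0552. The call of Taf9b was also lost without day 1 replicate 1 (0.0646) or 3 (0.0774). Each of the other 7 named genes lost its call in 8 to 11 of the 12 fits that left out 1 array, with limma adjusted p of 0.0506 to 0.254. With the replicate number as a block, which the correlation of equally numbered arrays allows here, 24 genes changed, of which 20 rose and 4 fell.

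Day 2 against day 0 gave 2228 changed genes, of which 1473 rose and 755 fell, so that 66.1% were rises. At least a 2-fold rise was seen for 314 genes and a 2-fold fall for 48. The arrays of the days did not overlap for 38.9% of genes, where chance gives 10%. The balance of rises and falls depended on the scaling between arrays. It was 1185 rises and 1357 falls (46.6% rises) with scaling to the 75th percentile, 1599 and 746 (68.2%) with cyclic loess, and 999 and 24 (97.7%) with no scaling. With no scaling the median change of all genes was itself 0.27. Among changed genes with another detected probe, that probe pointed the opposite way for 5 of 758. Of the 8 rises named, 3 were of genes detected at both days, which were Adssl1 (2.05 ± 0.13), Mlycd (2.00) and Tmem53 (1.97). The other 5 genes were undetected at day 0, so only bounds are given and they are not ranked against the former. They were Nrip3 (at least 2.67-fold), Sstr2 (at least 2.55-fold), Tex101 (at least 2.15-fold), Rassf5 (at least 2.08-fold) and Hba-a1 (at least 1.77-fold). After Hmox1, the largest falls were of Meis2 (-1.83), Sall3 (-1.57), Ubap1l (-1.56), H2-M5 (-1.38), Zfp428 (-1.34), Zfp423 (-1.32) and Setd1b (-1.32).

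Day 3 against day 0 gave 3889 changed genes, of which 2121 rose and 1768 fell (54.5% rises), with at least a 2-fold rise for 684 and a 2-fold fall for 285. The arrays did not overlap for 45.3% of genes, where chance gives 10%. Scaling to the 75th percentile gave 1841 rises and 2165 falls (46%), and no scaling gave 723 and 519. Another probe pointed the opposite way for 26 of 1429 changed genes. Among the rises named of genes detected at both days, that of Amn (ILMN_2675289) was the largest, from a mean log2 intensity of 6.67 ± 0.16 to 10.67 ± 0.22 (SD, n = 3), which was 16-fold, with a limma adjusted p of 8.97e-09. It was followed by Ttc9b (3.56, 11.8-fold), Slc38a5 (3.15, 8.86-fold) and Camk2n2 (2.97, 7.82-fold). The other 4 named genes were undetected at day 0, and their bounds were at least 6.38-fold for Sstr2, 4.68-fold for Crygd, 4.02-fold for Nrip3 and 3.89-fold for Actc1. Among the falls not given as bounds, that of Ubap1l (ILMN_2533444) was the largest, from 9.79 ± 0.12 to 5.95 ± 0.24, which was 14.3-fold lower, with a limma adjusted p of 4.07e-08. Meis2 (-2.93), Ccnd2 (-2.51), Accsl (-2.33), Fgf4 (-2.30), Slc6a15 (-2.28) and Prdm14 (-2.24) followed, and Vldlr, undetected at day 3, was at least 3.1-fold lower. The day 3 mean of Ubap1l lies near the detection limit, so its fold may be limited by the background. The dimmer Hdac2 probe, for example, was undetected at 5.92 on day 2 replicate 1 and detected at 5.96 on day 2 replicate 3.

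**Figure D1:**
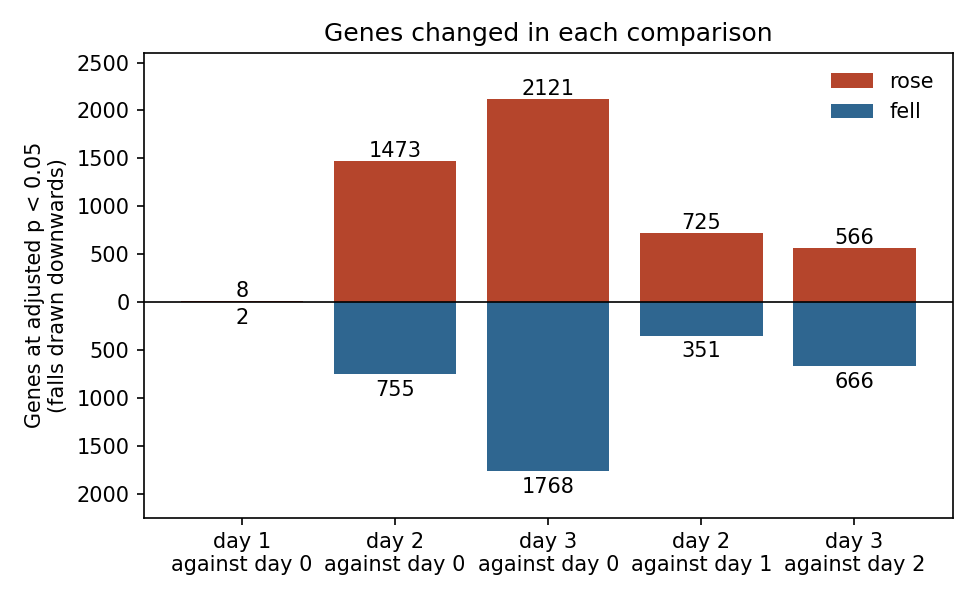
Genes at a limma adjusted p under 0.05 in each of the 5 comparisons, with rises drawn upwards and falls downwards on a linear count axis. Changed genes numbered 10 at day 1, 2228 at day 2 and 3889 at day 3 against day 0, and the split into rises and falls moved with the scaling between arrays (46.6% to 97.7% rises at day 2).

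**Figure D2:**
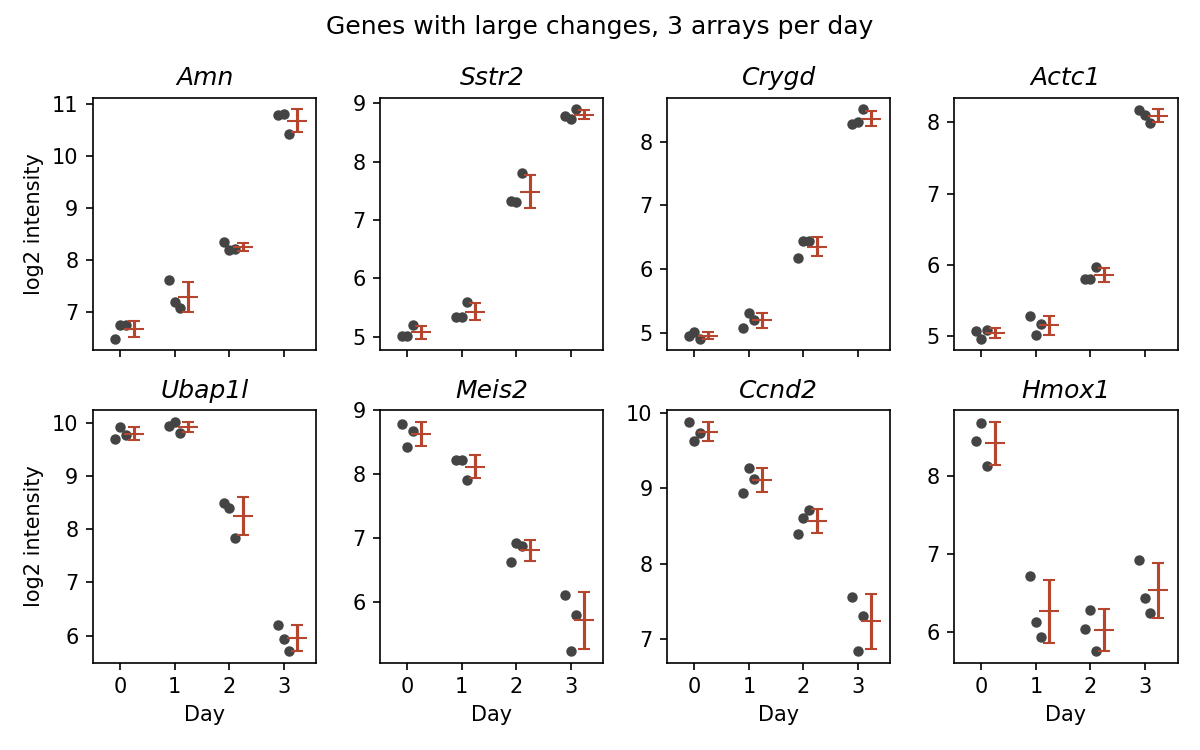
Log2 intensity of 8 genes with large changes by day, with a point per array and a bar for the mean and SD of 3 arrays. Hmox1 was lower from day 1 on, while Amn rose to 10.67 and Ubap1l fell to 5.95 by day 3.

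Most of the changes of day 2 were seen again at day 3. Of the genes called at both days, 1190 rose on both and 594 fell on both, where independent calls would give 314 and 134. Another 9 rose at day 2 and were lower at day 3, and 2 did the reverse. Both comparisons use the same 3 day 0 arrays, too few to be split between them, so part of this overlap can come from the shared controls. The covariance of the log2 fold changes across genes was 0.215, and 0.0163 in simulated arrays with no change, a difference of 0.199. These simulated arrays too were independent of each other, whatever their number.

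The steps between later days trace the course in time. Day 2 against day 1 gave 1076 changed genes, of which 725 rose and 351 fell (67.4% rises), with 580 and 613 (48.6%) under scaling to the 75th percentile and 369 and 2 with no scaling, where the median of all genes moved by 0.29. Gal (1.67) and Lbh (1.66) rose, as did Nrip3 (at least 2.66-fold), Sstr2 (at least 2.55-fold) and Mxra7 (at least 2.12-fold), which were undetected at day 1, and Ubap1l (-1.68), Meis2 (-1.31), Sall3 (-1.23), Rab26os (-1.22) and Gtf2a1 (-1.21) fell most. The count was 622, 516 and 645 without day 1 replicates 1, 2 and 3, and 595 and 548 without day 2 replicates 2 and 3. Day 3 against day 2 gave 1232 changed genes, of which 566 rose and 666 fell (45.9% rises). With no scaling these were 22 and 165, and the median of all genes moved by -0.36. Akr1cl (2.44), Amn (2.42), Actc1 (2.23), Crygd (2.01) and Krtdap (1.95) had the largest fitted rises. At day 2, Akr1cl was detected on 2 of 3 arrays and Actc1 and Krtdap on 1 each, so their rises start near background. Ubap1l (-2.28), Tmc7 (-2.12) and Hsd17b1 (-1.83) fell, as did Vldlr (at least 2.38-fold lower) and Stc1 (at least 2.14-fold lower), which were undetected at day 3. This count was 725 and 586 without day 2 replicates 2 and 3, and 771 and 616 without day 3 replicates 1 and 2. Across the steps, 117 genes rose in both, 48 fell in both, 69 rose and then fell, and 22 fell and then rose. The correlation of the steps across genes was 0.038, and -0.5 in independent simulated arrays with no change, since both steps share the day 2 arrays.

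Pluripotency factors were tested because the cells are embryonic stem cells kept in LIF. Of 30 measured, 1 rose and 13 fell at day 3, and the same numbers did so adjusted over the list alone. Their median change was -0.27, with a camera adjusted p of 0.00307 (adjusted p = 0.0553 with an estimated correlation). Pou5f1 went from a mean log2 intensity of 13.57 ± 0.20 to 12.91 ± 0.28 (SD, n = 3), a change of -0.67 ± 0.15 with a limma adjusted p of 0.00331. Sox2 changed by -0.80 ± 0.14 (limma adjusted p of 0.000863) and Nanog by -0.73 ± 0.18 (limma adjusted p of 0.00704). The largest falls were of Fgf4 (-2.30), Prdm14 (-2.24) and Gdf3 (-1.60). Sall1 (-0.81), Zfp42 (-0.66), Jam2 (-0.64), Esrrb (-0.57), Lefty1 (-0.48), Nr5a2 (-0.48) and Dppa4 (-0.43) also fell, and Mybl2 rose by 0.40. The calls of Jam2 (0.0588) and Dppa4 (0.0521) were lost without day 3 replicate 2. That of Mybl2 was lost without day 0 replicate 1 (0.0608) or day 3 replicate 2 (0.0639). Nr5a2 was lost without day 0 replicate 1 (0.0732) or 3 (0.13) and without day 3 replicate 1 (0.0821), 2 (0.0787) or 3 (0.054). Of the 16 members that did not pass, Dppa2 passed without day 3 replicate 3 (-0.63, limma adjusted p of 0.0341). Fbxo15 passed without day 3 replicate 1 (-0.35, limma adjusted p of 0.0485). The day 3 values of the other members that did not pass are not given singly. Without day 3 replicate 2, 0 members rose and 10 fell. At day 2, 2 members rose (Lefty1 and Lefty2) and 7 fell, and the list was not called, with a camera adjusted p of 0.225. The 7 falls were 3 without day 0 replicate 1 and 4 without day 2 replicate 2.

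**Figure D3:**
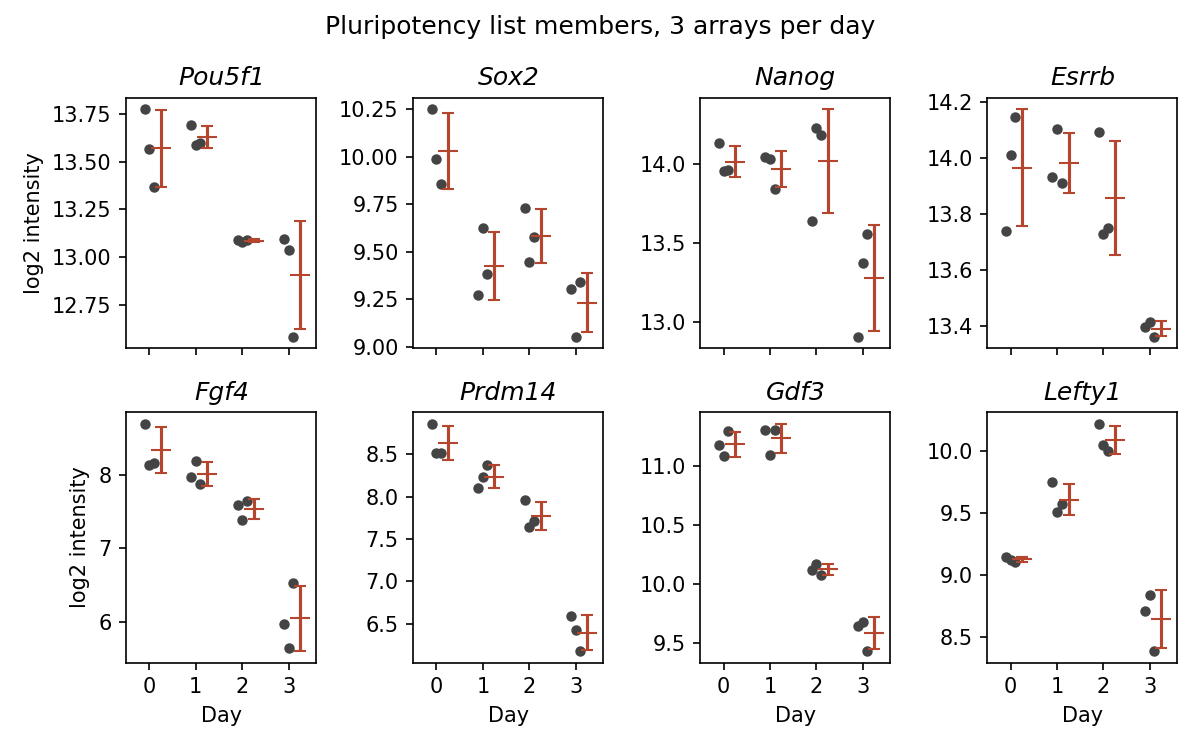
Log2 intensity of 8 pluripotency list members by day, with a point per array and a bar for the mean and SD of 3 arrays. Pou5f1 went from 13.57 at day 0 to 12.91 at day 3, Fgf4 and Prdm14 fell by more, and Lefty1 was higher at day 2 and lower at day 3.

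Of the 33 lists, camera called 1 at day 1, 10 at day 2 and 9 at day 3. With an estimated correlation between genes only the cytoskeleton and adhesion list at day 3 was kept, and 0 lists at days 1 and 2 were. The estimate was under the preset 0.01 for 2-cell-stage (-0.072), immediate-early (-0.063), interferon (-0.042), germline (-0.03) and lysosome (-0.012) lists. It was also under it for unfolded protein (-0.012), cytoskeleton (-0.004) and pluripotency (0.002) lists, so a higher correlation cost none of these lists a call. Their adjusted p rose although the correlation did not, so this setting differs from the preset in more than the correlation. A call of these lists lost with an estimated correlation is therefore no sign of correlated genes. The estimate was 0.21 for histone, 0.197 for REST, 0.084 for HDAC inhibitor, 0.066 for trophectoderm and 0.027 for histone acetyltransferase lists. The call at day 1 was of histone genes, with a median change of 0.29 over 44 genes and 0 called members over all genes or adjusted over the list alone (camera adjusted p of 7.41e-06; adjusted p = 0.324 with an estimated correlation). With fry it had an adjusted p of 0.0907. No called list's median changed sign under cyclic loess, the 75th percentile, no scaling, no background correction or the deposited values. The sizes moved. With no scaling, which put the median of all genes at 0.27 at day 2, that of histone acetyltransferases was -0.04 at day 2, which was -0.30 relative to all genes, against -0.37 with quantile normalization. The 75th percentile and no scaling differ by a factor per array, which moves all genes alike. Relative to all genes they give equal medians by construction and do not test the overall level of an array. Relative to all genes, 0 of the 20 medians called against day 0 moved by over 1.5 times with cyclic loess, the 75th percentile or no scaling. With no background correction, those at day 2 went from -0.37 to -0.25 for histone acetyltransferases, from 0.28 to 0.19 for germline genes, from 0.59 to 0.31 for 2-cell-stage genes and from 0.41 to 0.22 for interferon response genes. Those at day 3 went from 0.72 to 0.38 for REST-repressed neuronal genes and from 0.74 to 0.49 for 2-cell-stage genes, and that of histone genes at day 1 went from 0.26 to 0.17. With members undetected in 1 group set to their bound, the median of interferon response genes at day 2 was 0.28 in place of 0.44 and that of trophectoderm markers 0.29 in place of 0.33, while the other called medians stayed as they were. For every called list except the interferon response, whose highest adjusted p was 0.138 without the arrays numbered 3, the highest adjusted p over its 27 alternatives was that with the estimated correlation.

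At day 2, histone genes had a median of 0.50 with 21 rises and 1 fall (23 and 1 adjusted over the list alone; camera adjusted p of 2.38e-05; adjusted p = 0.272 with an estimated correlation). Genes reported to rise with HDAC inhibitors had a median of 0.52, with 9 rises and 0 falls among 13 (10 and 0 adjusted over the list alone), a camera adjusted p of 0.00086, and adjusted p = 0.109 with an estimated correlation. Lysosome and autophagy genes had a median of 0.40 with 9 rises and 0 falls among 24 (11 and 0 over the list alone; adjusted p of 0.00129; adjusted p = 0.0533 with an estimated correlation). Cytoskeleton and adhesion genes had a median of 0.33 with 10 rises and 0 falls among 26 (14 and 0 over the list alone), a camera adjusted p of 0.00173, and adjusted p = 0.0533 with an estimated correlation. The 2-cell-stage genes had 5 rises and 0 falls among 7 (6 and 0 over the list alone), a camera adjusted p of 0.00713, and adjusted p = 0.101 with an estimated correlation. The rises were 3 without day 0 replicate 2 or day 2 replicate 3. Immediate-early genes had 5 rises and 1 fall among 9, also adjusted over the list alone, a camera adjusted p of 0.0107, and adjusted p = 0.101 with an estimated correlation. Histone acetyltransferases had 0 rises and 3 falls among 8, also adjusted over the list alone, a median of -0.35, a camera adjusted p of 0.0303, and adjusted p = 0.127 with an estimated correlation. This call was lost without day 2 replicate 2 (0.0647). The single falls of the histone and immediate-early lists were 0 in some fits that left out 1 array.

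Germline genes (8 rises and 2 falls among 20, also adjusted over the list alone), trophectoderm markers (8 and 1 among 19, and 10 and 2 adjusted over the list alone) and interferon response genes (7 and 2 among 14, and 8 and 2 adjusted over the list alone) each had a camera adjusted p of 0.039 at day 2. They had adjusted p = 0.126, adjusted p = 0.272 and adjusted p = 0.126 with an estimated correlation. The germline call was lost with array weights (0.0557) and without day 0 replicate 3 (0.0671), day 2 replicate 1 (0.0642), day 2 replicate 2 (0.0564), day 3 replicate 2 (0.0634) or day 3 replicate 3 (0.0551). The trophectoderm call was lost without day 0 replicate 2 (0.0781), day 2 replicate 1 (0.0573), day 2 replicate 2 (0.0542), day 3 replicate 2 (0.056) or day 3 replicate 3 (0.0537). The interferon call was lost with no filter (0.0588), with detection on all 12 arrays (0.0864) and with array weights (0.0557), and without day 0 replicate 3 (0.102), day 2 replicate 1 (0.0642) or day 3 replicate 1 (0.0585), 2 (0.0603) or 3 (0.0551). The falls of germline genes were 1 without day 2 replicate 3, and the fall among trophectoderm markers was 0 without day 0 replicate 2 or 3 or day 2 replicate 2 or 3.

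At day 3, cytoskeleton and adhesion genes had 16 rises and 0 falls among 26 (17 and 0 adjusted over the list alone), a median of 0.40, a camera adjusted p of 0.000424, and adjusted p = 0.0405 with an estimated correlation. Myl9 (1.33), Acta1 (1.32), Lgals1 (1.08) and Zyx (1.05) rose most. Histone acetyltransferases had 0 rises and 6 falls among 8 (0 and 7 over the list alone), with a median of -0.68, a camera adjusted p of 0.00612, and adjusted p = 0.0746 with an estimated correlation. The largest falls were of Kat2b (-1.12), Ep300 (-0.93), Kat5 (-0.87) and Kat2a (-0.70). The unfolded protein and integrated stress response list had 1 rise and 8 falls among 17, also adjusted over the list alone (camera adjusted p of 0.0092; adjusted p = 0.0727 with an estimated correlation), with falls of Chac1 (-1.93), Trib3 (-1.07), Sesn2 (-1.03) and Vldlr (at least 3.1-fold lower). Lysosome and autophagy genes had 11 rises and 2 falls (12 and 2 over the list alone; adjusted p of 0.0127; adjusted p = 0.0727 with an estimated correlation), with rises of Ctsh (2.17), Ctsl (1.29), Map1lc3a (1.14) and Sqstm1 (0.95). The 2 falls were 0 without day 0 replicate 3 or day 3 replicate 2, and 1 in 7 of the other fits that left out 1 array.

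Histone genes at day 3 had 14 rises and 1 fall (13 and 1 adjusted over the list alone), a median of 0.31, a camera adjusted p of 0.0168, and adjusted p = 0.464 with an estimated correlation. The call was lost with no scaling (median 0.18, adjusted p of 0.145), with array weights (0.0562), without day 0 replicate 1 (0.0743, with 8 rises) and without day 3 replicate 2 (0.0521, with 6 rises). The rises were 22 without day 0 replicate 3 and also with the replicate block. The 2-cell-stage genes had 5 rises and 0 falls, also adjusted over the list alone, with a camera adjusted p of 0.022 and adjusted p = 0.107 with an estimated correlation. Tcstv1 (1.5), Zscan4c (1.38), Tcstv3 (1.20) and Arg2 (0.75) rose most. REST-repressed neuronal genes had 8 rises and 0 falls among 12 (8 and 1 over the list alone), a median of 0.72, a camera adjusted p of 0.0253, and adjusted p = 0.309 with an estimated correlation. Nefm (1.70), Vgf (1.33), Chga (1.17) and Syp (1.12) rose most. This call was lost without day 0 replicate 3 (0.0675) and without day 3 replicate 2 (0.0521). Trophectoderm markers had 10 rises and 2 falls (11 and 3 over the list alone; adjusted p of 0.0253; adjusted p = 0.242 with an estimated correlation), with rises of Rhox6 (1.39), Fgfr2 (1.17), Rhox9 (1.14) and Gata3 (at least 1.71-fold). The falls were 1 without day 0 replicate 2 or day 3 replicate 2.

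**Figure D4:**
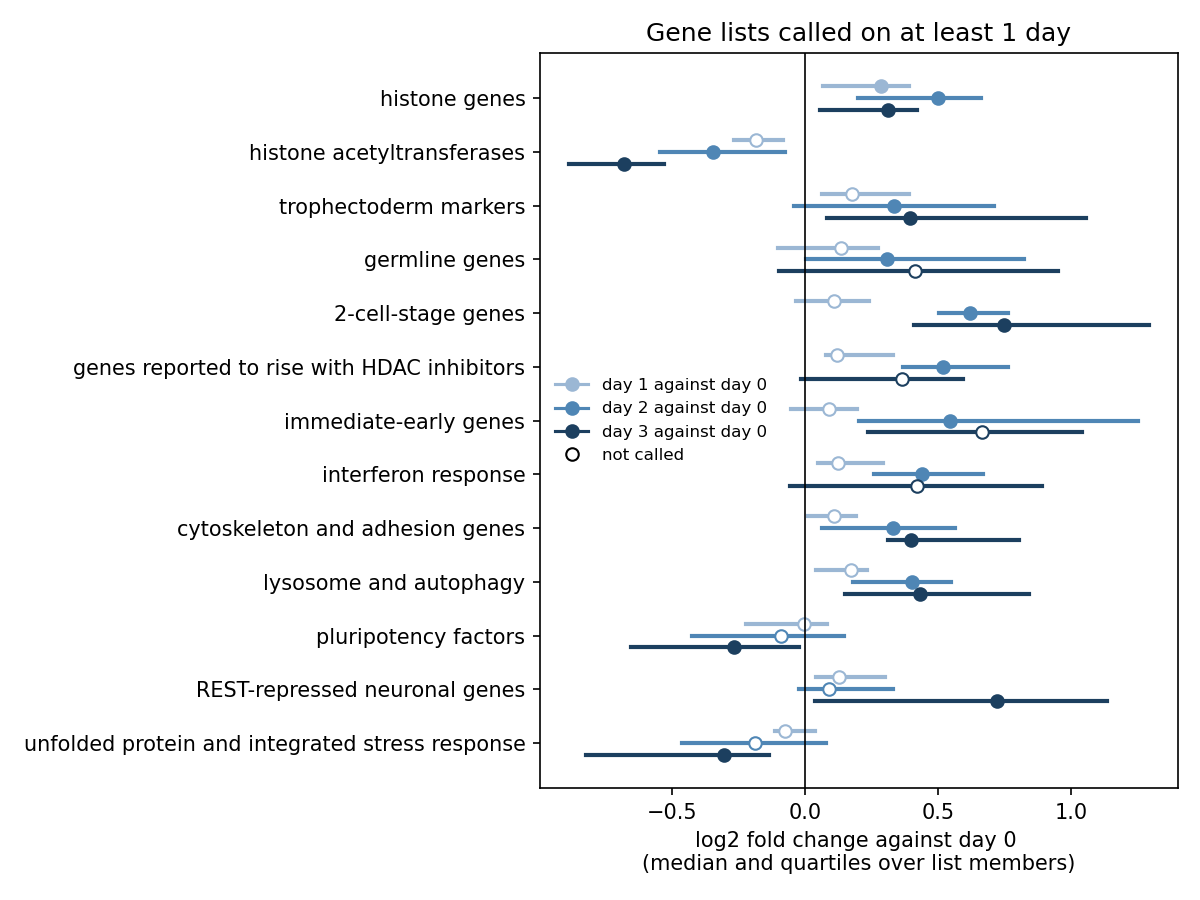
Median (point) and quartiles (line) of the log2 fold change against day 0 over the members of each list called on at least 1 day, with open points where the list was not called. Histone acetyltransferases reached a median of -0.68 and REST-repressed neuronal genes 0.72 at day 3, calls that were lost with an estimated correlation (adjusted p = 0.0746 and adjusted p = 0.309), and no called median changed sign under the scalings or background settings tried, though that of the REST list was 0.38 relative to all genes with no background correction.

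HDAC1 and HDAC2 are parts of repressor complexes, so the number of detected probes was compared. It was 15506 ± 462 (SD, n = 3) at day 0. It was 15495 ± 528 at day 1 (exact permutation p of 1, n = 3), 16497 ± 447 at day 2 (exact permutation p of 0.1, the smallest possible, n = 3) and 15818 ± 1134 at day 3 (exact permutation p of 0.6, n = 3). The difference at day 3 was 312 probes, -25 without day 3 replicate 3 and 967 without day 3 replicate 2. At day 2, 398 probes were detected on all 3 arrays and on none of day 0, and 41 showed the reverse, which were 314 and 121 at day 3 and 29 and 19 at day 1. By chromosome, limma's camera called 0 of 20 chromosomes at day 3, with 1 at an unadjusted p under 0.05 and a lowest adjusted p of 0.696.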

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

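The tests of scaling behind the excess of rises, of array brightness, of fibroblasts, of visceral endoderm cells, of the arrays' background, of S phase and of probes shared between histone copies, and the fits of lists between later days that left out 1 array, were chosen only after the result was seen.

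Genes came up here because the change from one later day to the next, which is the difference between their effects against day 0, passed limma's threshold itself. From day 1 to day 2 only the genes named as largest at day 1 or in that step were considered. Of these, Sstr2 (2.06), Nrip3 (1.87), Mxra7 (1.80), Gal (1.67), Lbh (1.66), Snorc (1.01), Myl2 (1.00), Elavl3 (0.77), Hmgn3 (0.59) and Taf9b (0.51) were higher at day 2. Ubap1l (-1.68), Meis2 (-1.31), Sall3 (-1.23), Rab26os (-1.22), Gtf2a1 (-1.21) and Myo10 (-0.44) were lower at day 2. These genes were picked for large changes, some of them in this step. Sstr2, Nrip3 and Mxra7 were undetected at day 1, so their fitted values depend on the background and are no bounds, which are at least 2.55-fold, 2.66-fold and 2.12-fold.

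From day 2 to day 3, 74 of the 194 named genes differed, 42 of them higher and 32 lower at day 3. The named genes were picked for large changes, some of them in this step, so this is no share of genes at large. Over all genes tested, 12.4% differed (566 higher and 666 lower). Of the 148 genes named from a list alone, most of which were also picked by the size of their change at day 3, 50 differed (31 higher and 19 lower). Among the 74 genes, several lay near the threshold, with limma adjusted p of 0.0496 (Rhox9), 0.0493 (Myo10), 0.0461 (H4f16) and 0.0459 (Rfc3). Without day 2 replicate 3 the count over all genes was 586 in place of 1232. Single genes were refitted with an array left out only for the 5 largest rises and 5 largest falls of this step. The largest fitted rises were of Akr1cl (2.44), Amn (2.42), Actc1 (2.23), Crygd (2.01), Krtdap (1.95), Rsad2 (1.76), Ttc9b (1.61), Slc38a5 (1.56), Nnat (1.47), Camk2n2 (1.40), Sstr2 (1.32), Myl9 (1.27), Vgf (1.26) and Nefm (1.11). Fgfr2 (0.93), Syp (0.85), S100a6 (0.83), H4f16 (0.82), Dnmt3l (0.78), Taf7l (0.76), Tcstv1 (0.76), Chga (0.75), Thy1 (0.71), Zyx (0.71), Cited1 (0.70), Hmgn3 (0.69), Fdps (0.68), Crip2 (0.67), Rhox6 (0.63), Rfc3 (0.63), Map1lc3a (0.61), Suds3 (0.56), Zscan4c (0.53), Rhox9 (0.52), Ebp (0.51), Phc2 (0.49), Igf2 (0.46), Hspb1 (0.45), Ccn2 (0.38), Cldn6 (0.35) and Ndufa8 (0.35) rose by less. Zfp423 rose by 0.71 after its fall at day 2, from -1.32 to -0.62 against day 0. Rsad2 was undetected at day 2, and its bound was at least 2.45-fold. Akr1cl was detected on 2 of 3 day 2 arrays and Actc1 and Krtdap on 1 each, so their fitted rises start near background.

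The falls from day 2 to day 3 were led by Ubap1l (-2.28), Tmc7 (-2.12), Vldlr (-1.83), Hsd17b1 (-1.83), Stc1 (-1.69), Fgf4 (-1.50), Lefty1 (-1.44), Prdm14 (-1.38), Ccnd2 (-1.33), Accsl (-1.14), Chac1 (-1.13), Meis2 (-1.10) and Slc6a15 (-1.09). Slc2a1 (-0.99), Lefty2 (-0.92), Tet1 (-0.87), Phc1 (-0.86), Snorc (-0.79), Jam2 (-0.76), Nanog (-0.74), Eno3 (-0.71), Egr1 (-0.68), Asz1 (-0.65), Trib3 (-0.61), Stk31 (-0.60), Ccne2 (-0.59), Gdf3 (-0.54), Gatad2b (-0.52), Zfp42 (-0.50), Esrrb (-0.47), Grb10 (-0.43) and Myo10 (-0.37) fell by less. Lefty1 went from 0.96 to -0.48 against day 0 and Tmc7 from 0.88 to -1.24. Vldlr, Stc1 and Gatad2b were undetected at day 3, so their fitted falls are no bounds. Vldlr was at least 2.38-fold lower and Stc1 at least 2.14-fold lower, while for Gatad2b no fall beyond the detection limit was shown. Stc1 was undetected at day 0 as well and at least 2.07-fold higher at day 2.

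Gene lists that differed between later days came up in the same way, with camera, and the median of none of them changed sign under cyclic loess, the 75th percentile, no scaling, no background correction or the deposited values. Their sizes moved. Relative to all genes, that of HDAC inhibitor genes from day 1 to day 2 went from 0.31 to 0.20 with the 75th percentile or no scaling. With no background correction, that of germline genes in this step went from 0.26 to 0.15, and that of REST-repressed neuronal genes from day 2 to day 3 from 0.49 to 0.25. The median of histone genes from day 1 to day 2 was itself 0.05 with the 75th percentile, which was 0.13 relative to all genes. From day 1 to day 2 the medians of 8 lists rose, and 0 of these calls were kept with an estimated correlation. They were immediate-early genes (0.60, adjusted p of 0.0022; adjusted p = 0.0701 with an estimated correlation), 2-cell-stage genes (0.53, 0.00678; adjusted p = 0.0701 with an estimated correlation) and genes reported to rise with HDAC inhibitors (0.32, 0.00509; adjusted p = 0.129 with an estimated correlation). Germline genes (0.27, 0.0131), lysosome and autophagy (0.26, 0.00902) and cytoskeleton and adhesion genes (0.24, 0.00541) each had adjusted p = 0.0701 with an estimated correlation. The last were p53 target genes (0.27, 0.0137) and histone genes (0.19, 0.0137), with adjusted p = 0.0904 and adjusted p = 0.503 with an estimated correlation. Members that rose, with those adjusted over the list alone in parentheses, were 5 of 9 immediate-early genes (5), 4 of 7 2-cell-stage genes (5), 6 of 13 HDAC inhibitor genes (7), 6 of 20 germline genes (8), 5 of 24 lysosome and autophagy genes (6), 5 of 26 cytoskeleton and adhesion genes (8), 4 of 25 p53 targets (4) and 3 of 44 histone genes (3). Of these lists 0 members fell, and adjusted over the list alone 1 HDAC inhibitor gene did. The rises were 3 for immediate-early genes without day 1 replicate 2, 2 for 2-cell-stage genes without day 1 replicate 1 or any 1 day 2 array, and 3 for HDAC inhibitor and for germline genes without day 2 replicate 2. They were 3 for lysosome and autophagy genes without day 1 replicate 1 or 2 or day 2 replicate 3, and 3 for cytoskeleton and adhesion genes without day 1 replicate 2 or 3 or day 2 replicate 3. They were 1 for p53 targets without any 1 day 1 array or day 2 replicate 3, and 2 without day 2 replicate 1 or 2, and 1 for histone genes without day 2 replicate 2. The histone call was also lost without day 1 replicate 1 (0.0833) or day 2 replicate 2 (0.0582), and with the background group of the arrays as a block (0.0733).

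From day 2 to day 3, the medians of p53 target genes (-0.36, camera adjusted p of 0.000123), glycolysis (-0.31, 0.000123) and pluripotency factors (-0.25, 0.00022) were negative, and these calls were kept, each with adjusted p = 0.0189 with an estimated correlation. The p53 target and glycolysis lists were not called against day 0. Their camera adjusted p were 0.225 and 0.298 at day 2, and 0.194 and 0.132 at day 3. The p53 list was called higher from day 1 to day 2. Both steps share the 3 day 2 arrays, so a deviation of those arrays alone could give both p53 calls. The calls of REST-repressed neuronal genes (0.48, 0.00251; adjusted p = 0.312 with an estimated correlation) and of the unfolded protein and integrated stress response (-0.22, 0.0189; adjusted p = 0.102 with an estimated correlation) were not kept. Of the REST list 6 members rose and 0 fell, of 12 (6 and 0 adjusted over the list alone), and of the unfolded protein list 0 rose and 4 fell, of 17 (0 and 4 adjusted over the list alone). Of the pluripotency factors 0 rose and 9 fell, of 30 (1 and 11 adjusted over the list alone). The REST rises were 3 without day 2 replicate 2 or 3 or day 3 replicate 2, and the pluripotency falls were 5 without day 2 replicate 3 or day 3 replicate 1 or 2. Of the p53 targets 0 rose and 8 fell, of 25 measured (1 and 14 adjusted over the list alone), and of the glycolysis genes 0 rose and 6 fell, of 17 (0 and 10 adjusted over the list alone). The 8 falls of p53 targets rested on single arrays. They were 1 without day 2 replicate 3 or day 3 replicate 2, 3 without day 2 replicate 2, 4 without day 2 replicate 1 or day 3 replicate 1, and 5 without day 1 replicate 1 or 2, while the call of the list was kept in each of these fits. Without day 3 replicate 1, 1 p53 target rose.

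Probes with no gene name, which the comparisons of genes leave out, also changed. Of 2397 such probes detected, 341 passed limma's threshold at day 2 (186 higher and 155 lower), and 810 did at day 3 (352 higher and 458 lower). They came up because they lie outside the genes tested, and which transcripts they measure is not known here.

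More genes rose than fell at day 2 (66.1% rises), and more probes became detected on all arrays (398) than became undetected (41). Scaling between arrays stays open as a source of the excess of rises, since the lowest share of rises under 3 other scalings was 46.6%. That came with the 75th percentile, which put the median of all genes at -0.09, while no scaling gave 97.7% with a median of 0.27. The 2 settings differ only by 1 factor per array, and cyclic loess, which adjusts by intensity, gave 68.2%, so what stays open is the overall level set for each array. These shares count changes of any size. With quantile normalization 314 genes rose and 48 fell at least 2-fold, and such changes were not counted under the other scalings. Brighter day 2 arrays also stay open as a source of the newly detected probes, since the upper quartile of signal was higher than on the day 0 array of the same number for 3 of 3 numbers. The log2 ratios were 0.04, 0.46 and 0.10 for numbers 1, 2 and 3, so that a clear difference was seen for number 2 alone. At number 2 the day 0 array lies in the lower background group, with a lower quartile of 165.8. The day 2 array (184.3) and the day 3 array (180.4) lie in the higher one. These intensities are not background subtracted, and equal numbers of days 0 and 2 did not all correlate (0.04, -0.03 and 0.25). At day 3, where 314 probes became detected and 121 became undetected, brighter day 3 arrays are argued against, since the upper quartile was higher for only 1 of 3 numbers and by 0.05 at most on the log2 scale. A loss of repressor complexes may also raise more genes than it lowers. The tables do not separate that from the scaling at day 2, nor from OHT itself or from days in culture, for which there are no samples.

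Some genes used as markers of other tissues rose by day 3, such as Amn, Actc1, Crygd and Nefm, which were chosen for mention here after their values were seen. Of the lineage lists, trophectoderm markers and REST-repressed neuronal genes were called at day 3 (each adjusted p of 0.0253), and neither call was kept with an estimated correlation. The REST call was also lost without day 0 replicate 3 (0.0675) or day 3 replicate 2 (0.0521). The endoderm (0.234), mesoderm (0.194) and neuroectoderm (0.832) lists were not called, so a rise of markers of these lineages as a whole was not shown. Contaminating fibroblasts are argued against, since 0 of Col1a1, Col1a2 and Col3a1 were detected on all 3 day 3 arrays, and each was detected on 0 of them. In the fibroblast list, of which 10 of 21 genes were measured in these cells, Fbln2 (at least 3.25-fold), Thy1 (1.75) and S100a6 (1.42) rose while Fn1 fell (-0.57). Visceral endoderm cells that express Ttr and Afp abundantly are argued against, since 0 of Ttr, Afp and Apoa1 rose, and Ttr and Afp were detected on 0 day 3 arrays. Apoa1 was detected on 2 arrays at day 3 and 1 at day 0, with a change of -0.13 that was not called. Of the endoderm list, 14 of 26 genes were measured, of which 5 rose and 2 fell. Amn, with the largest measured rise (4.00), is itself on that list, whose mean of 0.40 lies above its median of 0.17. Cited1 (0.87) and Dab2 (0.85) rose too, while Sox7 fell (-0.80). The rises were 3 without day 0 replicate 1 or day 3 replicate 2. Endoderm cells without Ttr and Afp, and a change of some of these genes in the stem cells themselves, stay open. The background group of the arrays is argued against as the whole source, since 97.2% of all genes that rose at day 3 also rose with that group as a block, which also called 9 lists. Scaling moved the share of rises at day 3 to 46% but turned the sign of no called list. A release of silenced genes after loss of HDAC1 and HDAC2 may account for the rise of these single genes, as may the start of differentiation, OHT or days in culture. None of these was separated from the others.

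The median change of the 44 histone genes at day 2 was 0.50, with 21 rises, 1 fall and 22 members that did not pass. The call of the list was lost with an estimated correlation at day 2 (adjusted p = 0.272) and at days 1 and 3. The upper quartile of the DNA replication list was -0.006 (rounding to -0.01), below the lower quartile of the histone list (0.20). This argues against a larger share of cells in S phase only if transcripts of replication genes follow that share. The share was not measured, so S phase stays open. Scaling between arrays is argued against, since the histone median itself was 0.50 with quantile normalization, 0.51 with cyclic loess, 0.36 with scaling to the 75th percentile and 0.71 with no scaling. Above that of all genes it was 0.473, 0.476, 0.443 and 0.443. The last pair is equal by construction, since a factor per array moves all genes alike, so the 75th percentile adds no test of that difference. Its lowest value, 0.319, came with no background correction, which is not a scaling. Probes shared between histone copies stay open. The SD of the changes was 0.172 within a class and 0.258 between class means, a ratio of 0.665, which lies between the values set for either answer, so shared probes and separate changes of many copies cannot be told apart. A change of histone transcripts, or of the share of them with poly(A) tails, may underlie the pattern, and the design gives no test of which.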

How the results depend on the processing

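The background group as a block, the fits within each background group, the fit to the arrays numbered 1 and 2, and the blocks and left-out arrays for lists between later days were chosen only after the result was seen. The slide as a block was not run, because the tables give no slide. The background groups coincide with the order of the deposited columns. The arrays with higher background are in positions 1 to 6 and the others in positions 7 to 12. Whether they are separate slides or runs is not stated.

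Of the 210 named-gene values, the 20 list calls against day 0 and the Hdac2 value, 0 reversed as a called value under the alternatives run for them. The 210 values are those of named genes at day 3 against day 0 and the largest rises and falls of the other comparisons. Other values of list members at days 1 and 2, and the other flagged steps of single genes between later days, were not run. The 13 list calls between later days were run with an estimated correlation, fry, both blocks and each array left out in turn, and their medians also under the other scalings and background settings. Of 5597 values of named genes under 27 settings, 5249 stayed on their side of the threshold, 332 kept their direction and lost the call, 16 gained one and 0 called values reversed. Of the values called under neither setting, 25 changed sign. The counts of genes and lists not mentioned here stayed within 1.5 times their value. Counts within a background group are an exception and are left out, because some days have a single array there. Where a count below differs by construction, the reason is given, and in the other cases the cause was not tested.

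The count of day 1 genes was 10 and fell to 3 with no background correction and with the deposited normalized values (6 lists each). It was 17 with cyclic loess (2 lists), 1 with no scaling, 2 with no filter (5 lists), 2 at detection p under 0.05, 2 with every probe as its own feature, 2 with only the arrays of the 2 groups, and 34 with array weights (5 lists). Scaling to the 75th percentile gave 2 lists at day 1 and -0.456 for Hdac2 at day 3 (adjusted p of 0.00841, the lowest of its alternatives, which reached 0.426). With no scaling, 1023 genes changed at day 2, 1242 at day 3, 371 from day 1 to 2, 187 from day 2 to 3 and 1216 across the days. Every probe as its own feature, which tests more features, gave 6303 at day 3 (3066 higher and 3237 lower) and 5702 across the days. Day 3 against day 2 gave 624 with only the arrays of the 2 groups, which leaves fewer arrays. With array weights, 2030 changed from day 1 to 2 and 2112 from day 2 to 3.

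With the replicate block, 24 genes changed at day 1, and 1973 from day 2 to 3, where the arrays of the same number did not all correlate. A fold of at least 1.5, a stricter rule, left 1427 genes at day 2, 2590 at day 3, 687 from day 1 to 2 and 760 from day 2 to 3. An adjusted p under 0.01, also stricter, left 2 at day 1, 1123 at day 2, 364 and 407 in the steps, and 2197 across the days. An estimated correlation called 0, 0 and 1 lists at days 1, 2 and 3. With fry, which does not compare a list with other genes, 5, 21 and 25 lists were called.

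The 6 arrays with higher background gave 0 genes at days 1 and 2 (limma; 174 and 1445 at an unadjusted p under 0.05), 620 at day 3, 0 and 3 in the steps (1011 and 1604 unadjusted) and 158 across the days. The 6 with lower background gave 0 at day 1 (1113 unadjusted), 497 at day 2, 1983 at day 3, 0 in each step (1739 and 1468 unadjusted) and 801 across the days. These fits have fewer arrays. The background group as a block gave 13, 2319 and 4147 genes at days 1, 2 and 3. The arrays numbered 1 and 2 gave 0 at day 1 (1028 unadjusted) and 482 from day 1 to 2, with fewer arrays.

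Leaving out 1 array at a time gave 0 to 15 genes at day 1, 1580 to 2520 at day 2, 3241 to 3997 at day 3, 516 to 1297 from day 1 to 2, 586 to 1797 from day 2 to 3 and 3151 to 3996 across the days. The 0 came without day 0 replicate 2 (limma; 1001 unadjusted). Lists called were 1 to 3 at day 1, 7 to 11 at day 2 and 7 to 11 at day 3, and chromosomes 0 to 0. The Hdac2 change was -0.407 (without day 3 replicate 3, adjusted p of 0.0241) to -0.16 (without day 3 replicate 2). The difference in detected probes at day 3 was -25 (without day 3 replicate 3) to 967 (without day 3 replicate 2), so its sign rests on single arrays. Signal over background limits the folds of genes undetected in 1 group, which are lower bounds.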

Other observations

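The grouping of histone genes by class, and the fits that left out 1 array for the members of the lists, were chosen only after the result was seen.

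Histone genes are given by class at day 2. Of 8 H2B genes 7 rose, with a mean change of 0.69, and 6 of 8 H4 genes (0.64), 4 of 7 H3 genes (0.54), 3 of 4 H1 genes (0.69) and 1 of 10 H2A genes (0.12) did. Of 7 variants outside the clusters 0 rose and 1 fell, with a mean of 0.03. All H1 genes, in or outside the clusters, are counted in the H1 class and not among these variants. Over the scalings and background settings tried, the class means relative to all genes ranged from 0.61 to 0.67 for H2B, 0.46 to 0.63 for H4, 0.44 to 0.51 for H3 and 0.46 to 0.70 for H1. They ranged from 0.01 to 0.11 for H2A and from -0.09 to 0.02 for the variants, which changed sign. The differences between classes were not tested.

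The lists not called at day 3 moved in both directions, and members that rose or fell over all genes tested are given next, with counts adjusted over the list alone in parentheses. Among genes of the cell's lineage choices, 5 of 14 primitive and visceral endoderm markers rose and 2 fell (5 and 2), 5 of 8 primitive streak and mesoderm markers rose and 1 fell (5 and 1), 2 of 8 neuroectoderm markers rose and 1 fell (2 and 2), and 3 of 8 primed epiblast markers rose and 2 fell (3 and 2). The rises of endoderm markers were 3 without day 0 replicate 1 or day 3 replicate 2, and those of primed epiblast markers 1 without day 0 replicate 2 or day 3 replicate 1 or 3. Of 20 germline genes 11 rose and 2 fell (11 and 2), with a camera adjusted p of 0.0547. The germline list was called with the replicate block (0.0355) and without day 1 replicate 3 (0.0432), day 2 replicate 3 (0.0439) or day 3 replicate 1 (0.0412), and had adjusted p = 0.146 with an estimated correlation. Tex101 (at least 2.69-fold) and Taf7l (2.19) rose and Asz1 (-1.49) fell. Of 20 imprinted genes 7 rose and 3 fell (8 and 3), with Nnat at 2.00 and Igf2 at 1.13.

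In the cell cycle lists, 2 of 43 mitosis genes rose and 8 fell (2 and 6), 3 of 38 DNA replication genes rose and 6 fell (3 and 6), and 1 of 6 CDK inhibitors rose and 1 fell (1 and 1). Of 25 p53 target genes 3 rose and 6 fell (2 and 6), and of 19 apoptosis regulators 9 rose and 4 fell (10 and 4). The falls of mitosis genes were 4 without day 0 replicate 1 and 3 without day 3 replicate 1 or 2, and those of p53 targets 3 without day 0 replicate 1. In the chromatin lists, 6 of 27 HDAC1/2 corepressor subunits rose and 5 fell (6 and 5), 4 of 22 Polycomb subunits rose and 5 fell (4 and 5), and 1 of 10 DNA methylation genes rose and 1 fell (1 and 1). The falls of Polycomb subunits were 3 without day 0 replicate 1 or 3 and 2 without day 3 replicate 2. Phc2 rose by 1.25 while Phc1 (-1.18) and Tet1 (-1.33) fell.

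In the metabolic lists, 3 of 17 glycolysis genes rose and 7 fell (3 and 9), 4 of 34 oxidative phosphorylation genes rose and 1 fell (3 and 1), 8 of 16 cholesterol biosynthesis genes rose and 1 fell (8 and 1), and 1 of 37 cytosolic ribosomal proteins rose and 1 fell (1 and 1). The rises of cholesterol genes were 5 without day 3 replicate 1. Of 9 heat shock genes 3 rose and 3 fell (4 and 3), with Hspa1a at least 2.37-fold higher. Of 9 immediate-early genes 5 rose and 1 fell (5 and 2). Egr1 was 1.76 above day 0 at day 2 and 1.07 at day 3, and Myc was undetected at day 3 and at least 1.27-fold lower. The immediate-early list was called at day 3 without day 2 replicate 2 (0.033) or 3 (0.0382), and had adjusted p = 0.208 with an estimated correlation. Of 14 interferon response genes 7 rose and 2 fell (7 and 2), with Psmb9 at 1.42 and Rsad2 at least 2.14-fold higher, and the list was called without day 0 replicate 2 (0.0491; adjusted p = 0.182 with an estimated correlation and all arrays). Of 13 genes reported to rise with HDAC inhibitors 5 rose and 1 fell (7 and 1), with 8 rises under the replicate block, and of 10 fibroblast markers 4 rose and 2 fell (4 and 2). Counts of 1 or 2 in these lists often moved by 1 when 1 array was left out. The 2 falls of fibroblast markers, for example, were 0 without day 0 replicate 1 and 1 in 9 of the other fits that left out 1 array.

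Other splits of the arrays were counted beside the comparisons. For the genes changed across the 4 days, 1 of 100 drawn splits of the 12 arrays, the real one, gave as many as 3736, and the highest other gave 1564. Random labelling of these arrays is therefore argued against for that count. The labels do not say that the 3 arrays of a day are separate cultures. A difference in culture or handling between the days would give the same result and is not excluded. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real counts were 10, 2228, 3889, 1076 and 1232 for day 1, day 2 and day 3 against day 0, day 2 against day 1 and day 3 against day 2, and the highest other was 0 in each case. The other splits mix the days, so that the change between days enters the spread. Of the splits, 4 part all 3 pairs of equal numbers, and among these too the highest other was 0. The split that follows the background of the arrays gave 0 genes for days 2 and 3 against day 0 and for day 2 against day 1. For lists, 7 of the 10 splits gave as many as the 1 of day 1, with a highest other of 2. The 10 lists of day 2 and the 9 of day 3 were each reached by 1 split, with highest others of 4 and 5, and these splits too are too few for a share under 0.05.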
